A study of Mus musculus with 28 samples.

How the data were processed

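Gene expression was measured in whole lungs of newborn mice, collected on the day of birth (day 0), with 1 array for each of 28 individual animals. Per the labels, the arrays were 1-colour whole-transcript arrays hybridised with biotin-labelled fragments of total RNA, and the RNA was purified with TRIZOL and then on columns. The values used here are the log2 values the authors deposited, 1 per probe set and array, made with the robust multi-array average (RMA, which corrects background, normalizes arrays by quantiles and summarises the probes of a set) and the affy package per the submitters' processing notes, with versions not given in the sources used here. Whether all arrays were normalized together is not given in the sources used here either. The table held 41345 probe sets on 28 arrays. Array medians lay between 5.25 and 5.41, and the number of arrays, not a sequencing depth, limits the precision.

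Samples were grouped by their own labels into 8 groups: Control (3), HRas-KO (3), NRas-KO (3), DKO (5), Control+NAC (4), HRas-KO+NAC (3), NRas-KO+NAC (3) and DKO+NAC (4). A treatment note shared by all samples names only 3 of them as exposed to N-acetyl cysteine (NAC, 0.5% given to the pregnant females), while the sample labels assign NAC to 14 arrays, and the sample labels were followed. The titles of the 3 HRas-KO+NAC samples do not mention NAC while their source labels do, so that group and its comparisons rest on the source labels. Sample titles end in an animal code. The start of that code was read as a possible litter or collection batch, although the labels do not say what it stands for. No code start occurred in both an untreated and a NAC array, and none of the 3 code starts of the untreated DKO arrays occurred in another group. No 2 arrays held identical values, and the highest correlation among 378 pairs of arrays was 0.9933.

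Probe sets were named through the platform annotation: 23521 had 1 gene symbol, 1814 had several and 16010 were unlisted there. The brightest probe set stood for a gene, which left 22180 genes for testing, 1082 of them with several probe sets. Hras was not analysed here. limma 3.58.1 in R 4.3.3 fitted 8 group means to all 28 arrays together (lmFit, eBayes, 20 residual and 5.95 prior degrees of freedom), so that all groups shared 1 estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, in each of 14 comparisons. Adjusted p-values printed for genes come from this limma fit.

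Lists of genes for lung cell types, neighbouring tissues and pathways were fixed before the data were examined, 44 in all, with 720 of 798 written genes matched to a measured gene by current or older symbol and 43 lists holding 3 or more measured members. Of these matches 2 were to another gene that once bore the written symbol (B4galnt2 for Igf2bp1 among distal lung progenitors and Pigq for Gpi1 in glycolysis), so 718 written genes were measured. Both stayed in the lists tested, and all lists were tested again without them after seeing the data. The mitochondrially encoded list had none and was not tested. camera tested each list against all other genes with a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and list p-values were adjusted over the 43 lists. Sphingolipid and respiratory chain lists were written because the series title names those themes, so their direction is not independent evidence.

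Genes named in the text followed a rule fixed at the same time. Nras was always named. Called genes whose groups did not overlap were ranked by change. For DKO against control, DKO+NAC against DKO and DKO+NAC against control+NAC the 10 most raised and 10 most lowered were taken (5 and 5 elsewhere). Predicted genes, clone names, microRNAs, small nucleolar RNAs with symbols that begin with Snor, Xist and Y-linked genes were left out. Rnu3a, a small nucleolar RNA with another kind of symbol, stayed in. From each list described the 4 members with the smallest p were added, and where no gene passed, the 5 smallest p-values. Not every gene the rule allows is printed.

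Alternatives fixed beforehand covered all rows of the table, the mean of a gene's rows, a filter on the dimmest 40% of rows, quantile normalization again, array-median centring, trended and robust moderation, array weights, only the arrays of the groups compared, the replicate number as a block, the code start as a random or fixed block, each array left out in turn and a 1.5-fold minimum. Xist, muscle lists and small RNA rows as covariates, and fits without doubted arrays or within 1 code start, were added after seeing the data. Replicate numbers did not pair arrays: same-numbered arrays of different groups in 1 arm correlated at 0.021 on average over 37 pairs in their deviations from group means. Arrays of different groups in 1 arm that shared a code start correlated at 0.15 on average, with 15 of 28 pairs over 0.1, and those of other code starts at -0.035 over 117 pairs, so the code start went with a part of the variation within groups.

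The gene test was tested on simulated data, arrays with the real gene means and spreads, independent noise and 200 changed genes among 22180. For 5 against 3 arrays as in DKO against control, 58.2% of genes changed by 0.5 on the log2 scale and 97% of those changed by 1 were recovered. For 3 against 3 arrays as in HRas-KO against control the shares were 37.3% and 94%, and for 4 against 4 as in DKO+NAC against control+NAC they were 59.7% and 97%. Simulated noise was independent, without differences between code starts, so these shares describe the test and not the power of the real comparisons.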

Results

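Lungs of newborn mice were profiled to ask how the loss of the small GTPases HRas and NRas, alone or together, changes lung gene expression, and whether antenatal N-acetyl cysteine (NAC, an antioxidant and precursor of glutathione) alters this. The series title reports fatal respiratory distress in the double knockout (DKO). Untreated groups held 3 Control, 3 HRas-KO, 3 NRas-KO and 5 DKO arrays, and the NAC arm held 4 Control, 3 HRas-KO, 3 NRas-KO and 4 DKO arrays, each from 1 animal. Values are log2 RMA values, differences are log2 fold changes, and n counts animals.

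The targeted gene Nras (probe set 17401117) was lower on arrays of both genotypes that lack it. Its level was 8.24 ± 0.14 (SD, n = 3) in Control, 8.26 ± 0.13 (n = 3) in HRas-KO, 7.69 ± 0.10 (n = 3) in NRas-KO and 7.63 ± 0.13 (n = 5) in DKO. With NAC it was 8.33 ± 0.12 (n = 4) in controls, 8.29 ± 0.11 (n = 3) in HRas-KO, 7.70 ± 0.12 (n = 3) in NRas-KO and 7.75 ± 0.23 (n = 4) in DKO. The array labelled DKO+NAC replicate 4 read 8.08, above the other DKO+NAC arrays (7.56 to 7.74) and above the lowest Control array (8.07). Which part of Nras was deleted, and whether the probe set lies in it, is not given in the sources used here. The probe set still followed the labels. Every other NRas-KO and DKO array of both arms read 7.40 to 7.80, and every Control and HRas-KO array 8.07 or more. Why DKO+NAC replicate 4 read 8.08 was not tested. Hras was not analysed here, so the HRas-KO labels were not checked.

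**Figure D1:**
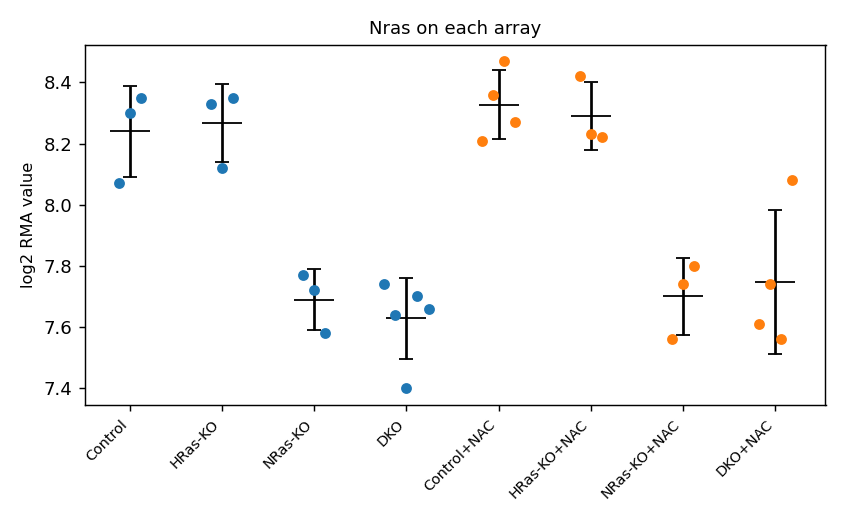
Nras on each array (points, log2 RMA value on the vertical axis) by group, untreated in blue and NAC in orange, with group means (lines) and SDs (bars). NRas-KO and DKO means lie between 7.63 and 7.75, the other groups between 8.24 and 8.33, and the array labelled DKO+NAC replicate 4 lies at 8.08.

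Untreated DKO lungs differed from Control in 850 of 22180 genes, 550 higher and 300 lower. Bst2 (tetherin, an antiviral membrane protein) was 6.78 ± 0.71 (n = 5) in DKO against 8.67 ± 0.14 (n = 3), a difference of -1.89 ± 0.28 (SE, adjusted p = 0.00029), and Iigp1 (-1.47), Oasl2 (-1.35) and Slfn4 (-1.39) also fell. Etv5, a transcription factor induced by ERK signalling and used by alveolar type 2 cells, fell by 1.18 ± 0.15 (adjusted p = 8.7e-05), and Nras itself fell by 0.61. Perp, a p53 target at cell junctions, rose by 1.17 ± 0.18 (adjusted p = 0.00049). Rabac1, a Rab GTPase-binding protein of the Golgi, rose by 1.16 ± 0.10 (adjusted p = 4e-07), from 8.61 ± 0.10 to 9.77 ± 0.18.

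Among the other most raised genes were the small RNAs Rnu3a (2.15) and Rny3 (1.38), Rasd1, a dexamethasone-induced Ras-like protein (1.43), Egln3, a hypoxia-induced prolyl hydroxylase (1.39), Pi15 (1.22), Pappa, a protease of insulin-like growth factor binding proteins (1.22), the complement regulator Cd59a (1.17) and the embryonic globin Hbb-y (1.15). Small nuclear, nucleolar and Y RNA rows as a set averaged 0.38 ± 0.28 (SD, n = 5) above their gene means in DKO and -0.24 ± 0.24 (n = 3) in Control. The most lowered genes also included Nes, the intermediate filament nestin (-1.64), Zfp781 (-1.48), the toll-like receptor 4 partner Ly96 (-1.35), the actin-binding Nexn (-1.27) and the growth factor Pdgfb (-1.24).

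By list, 7 of 14 interferon response genes fell in DKO and none rose (camera adjusted p = 6e-10). Besides Bst2 these included Stat2 (-1.03), Rtp4 (-1.08) and Isg15 (-1.01). Interferon list means were 0.66, 0.13 and 0.16 in Control replicates 1 to 3 and -0.53 to -0.26 in DKO. Control replicate 1, the highest, had another code start than Control replicates 2 and 3. HRas-KO replicate 3 lay at -0.16. Of 22 surfactant and alveolar type 2 genes 3 fell (adjusted p = 0.00016): Etv5, the apical mucin Muc1 (-0.62) and the lamellar body protein Lamp3 (-0.52), while the surfactant protein transcript Sftpc stood at 13.14 ± 0.07 (n = 5) in DKO and 13.08 ± 0.08 (n = 3) in Control, named here after its values were seen. Sftpc lay near the highest value of any probe set (13.55), where a change may go unseen. DKO replicates 1 and 3 had type 2 list means of -0.43 and -0.34, against 0.02, 0.05 and -0.07 in DKO replicates 2, 4 and 5 and 0.04 to 0.12 in Control. Their small RNA means were 0.42 and 0.85, against 0.19 to 0.24 in the other DKO arrays. Their skeletal muscle means were 1.41 and 0.48, against -0.12, -0.19 and 0.89 in DKO replicates 2, 4 and 5. DKO replicates 1 and 3 were also the only DKO arrays high in Xist (10.36 and 9.92, against 3.95, 4.33 and 4.06). Sex and these list differences were therefore not separable within DKO. Of 13 p53 targets 4 rose and 1 fell (adjusted p = 0.0047), with Perp, Tnfrsf10b (1.11) and Trp53inp1 (0.91) up and Phlda3 (-0.57) down. No member of the erythroid list of 10 passed on its own, although all 10 estimates were positive and the list was called upward (adjusted p = 0.00012). The cholesterol synthesis list was called upward (adjusted p = 0.043) with 1 of 16 members called, Fdft1 (0.70). With an estimated correlation no list was called: adjusted p = 0.13 for the interferon, erythroid and p53 lists, 0.45 for alveolar type 2 and 0.79 for cholesterol synthesis. With fry the type 2 and cholesterol calls were lost (adjusted p = 0.079 and 0.34), and with muscle lists as covariates the cholesterol call was (adjusted p = 0.28).

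**Figure D2:**
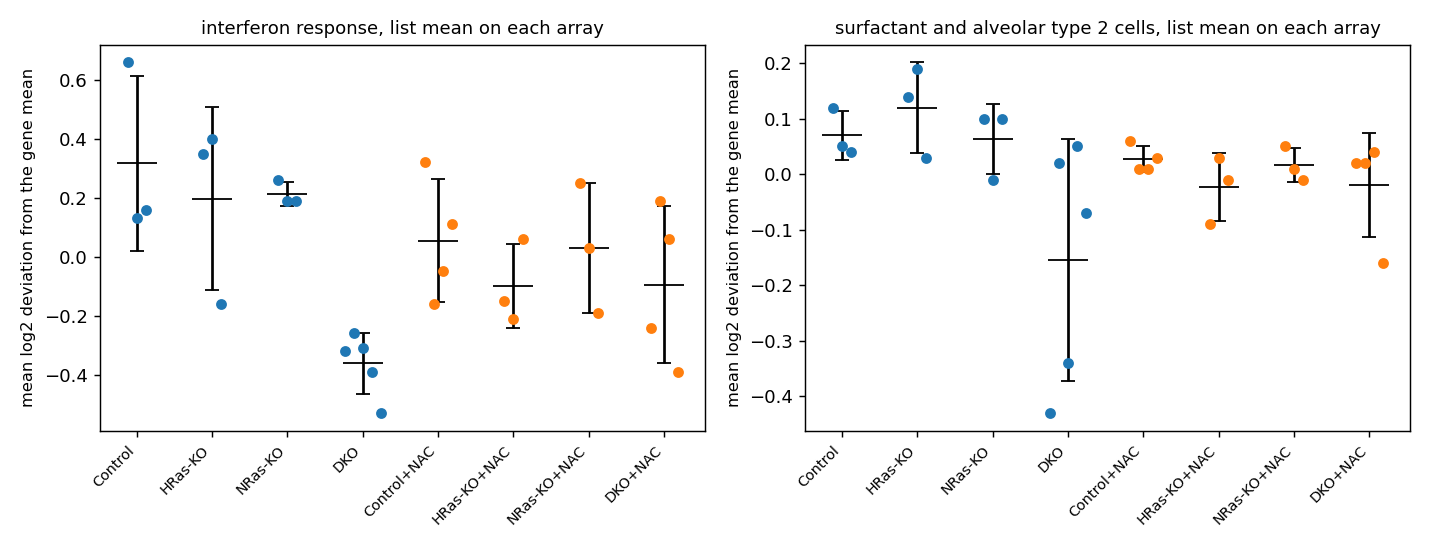
Mean of the interferon response list (left) and of the surfactant and alveolar type 2 list (right) on each array, as log2 deviation from each gene's mean over all arrays, with group means (lines) and SDs (bars). Interferon values of the 5 DKO arrays lie between -0.53 and -0.26 and those of Control at 0.66, 0.13 and 0.16. Type 2 values of DKO spread from -0.43 to 0.05.

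Sphingolipid genes, a theme of the series title and so no independent evidence, leaned upward: 6 of 45 rose, none fell and 39 were not called, or 8 up and 1 down adjusted over the list alone (camera adjusted p = 0.0082, and adjusted p = 0.077 with an estimated correlation). The ceramide synthase Cers5 rose by 0.65, the sphingosine kinase Sphk1 by 0.48, the desaturase Degs1 by 0.43 and the phosphatase Sgpp1 by 0.45. Oxidative phosphorylation, the other theme of the title, was not called in DKO. Complex I had 2 members higher and 1 lower of 33 (adjusted p = 0.63), complexes II and III 1 and 1 of 13 (adjusted p = 0.23), complex IV none of 16 (adjusted p = 0.27) and ATP synthase none of 16 (adjusted p = 0.56). In the list of ERK pathway targets, genes induced downstream of RAS, Etv5 and Ccnd1 (-1.03) fell among 18 and the list missed the threshold (adjusted p = 0.058).

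The cholesterol call was lost without Control replicates 1 and 3 or DKO replicates 1 and 3 (adjusted p = 0.13, 0.09, 0.21 and 0.11). The count of genes for DKO against control was 334 without Control replicate 1 and 321 without Control replicate 2, and 122 in a fit of those 8 arrays alone. It was 544 with muscle lists and 183 with small RNA rows as covariates, and 213 without the 5 arrays highest in skeletal muscle genes. No untreated DKO array shared a code start with another group, so genotype and collection batch cannot be told apart here. With arrays scaled by quantiles again the split was 450 higher to 438 lower. Skeletal muscle genes averaged 0.49 ± 0.68 (n = 5) in DKO and 0.17 ± 0.45 (n = 3) in Control.

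**Figure D3:**
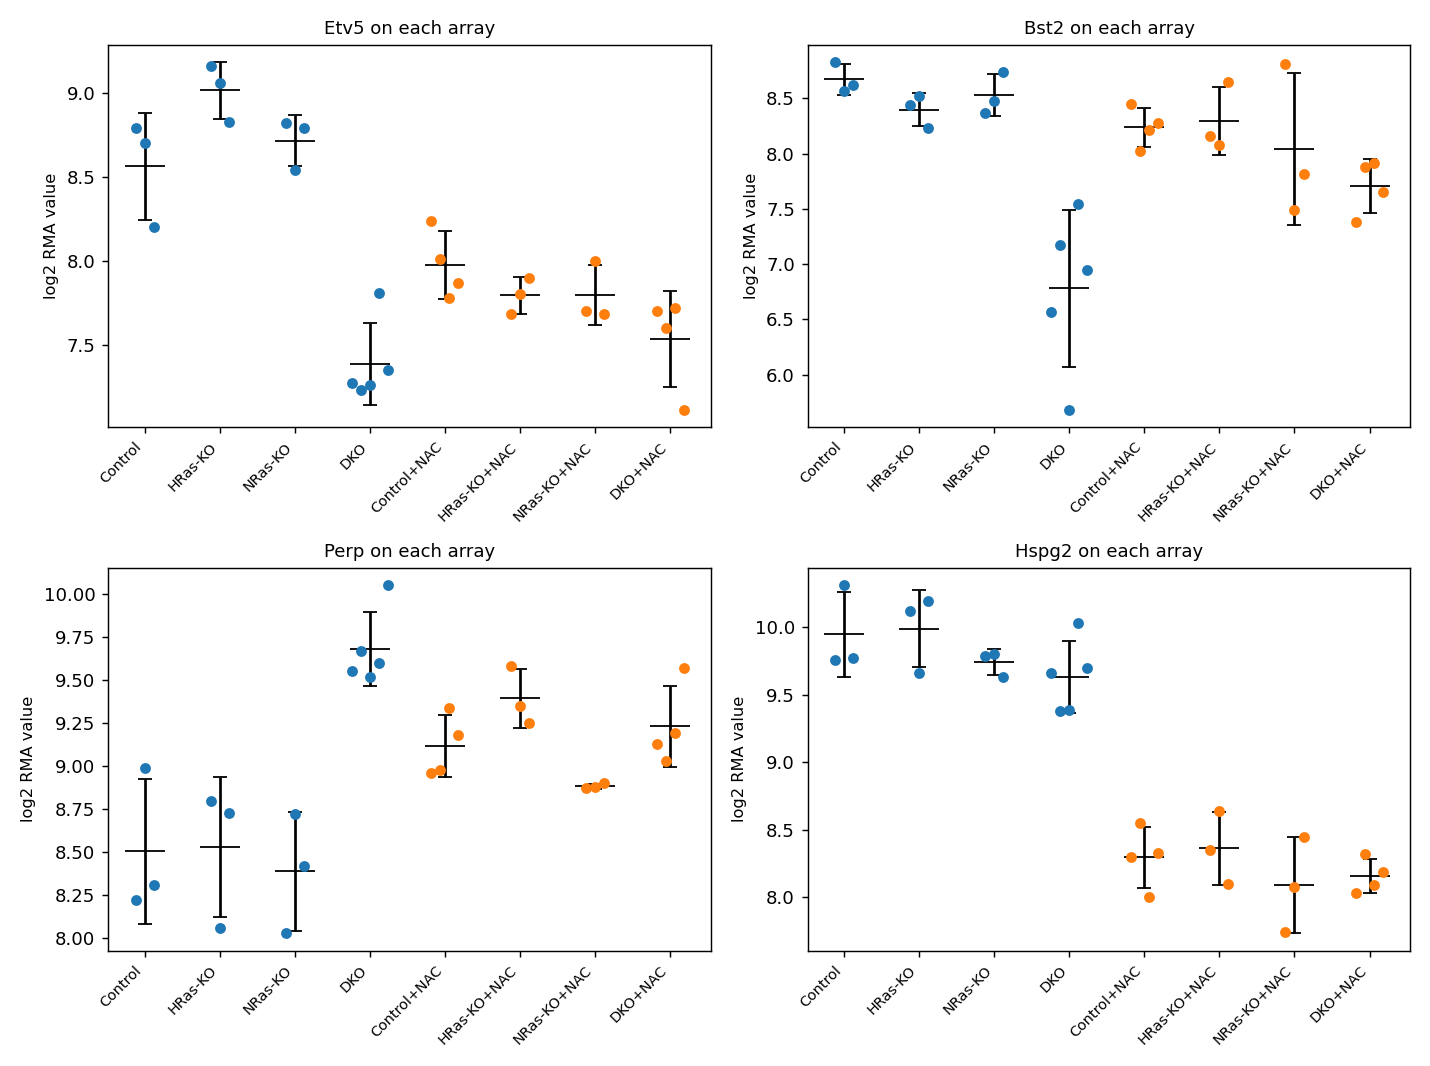
Etv5, Bst2, Perp and Hspg2 on each array (log2 RMA value), by group, untreated in blue and NAC in orange, with group means (lines) and SDs (bars). Bst2 averages 6.78 in untreated DKO and 7.71 or more in every other group, and Hspg2 averages 9.63 to 9.99 untreated and 8.09 to 8.36 with NAC.

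Neither single deletion gave a called gene against Control. HRas-KO had 190 genes and NRas-KO 231 at an unadjusted p under 0.05 in limma, where 1109 are expected by chance. Counts so far below chance point to p-values that ran too large, and the deleted Nras was itself not called in NRas-KO. The lack of called genes is therefore no evidence that a single deletion changes nothing. Smallest p-values in HRas-KO, none passing, belonged to Cav3 (0.36), Nefl (0.38), Nppa (2.83), Cd70 (-0.29) and Npn2 (-0.32). Nppa, an atrial hormone, came with the heart muscle list, called upward (camera adjusted p = 2e-04, adjusted p = 0.3 with an estimated correlation), with no member called alone. The ciliated, skeletal muscle and glucocorticoid lists were called downward in HRas-KO (adjusted p = 0.0038, 0.017 and 0.0041, and 0.92, 0.92 and 0.3 as adjusted p with an estimated correlation). In NRas-KO the smallest p-values belonged to the epidermal keratins Krt10 (2.50) and Krt1 (1.72), Ruvbl2 (0.43), Nras (-0.55, adjusted p = 1) and Pdk4 (-0.59), none passing.

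In NRas-KO the cell cycle list was called upward (adjusted p = 6.6e-06) and the neutrophil list downward (adjusted p = 0.012), with no member called, and both lost the call with an estimated correlation (adjusted p = 0.94 each). The glucocorticoid response list, genes induced by the hormone that matures the fetal lung, was called downward in NRas-KO (camera adjusted p = 1.9e-07, adjusted p = 0.013 with an estimated correlation), with Pdk4 and Fkbp5 (-0.52) lowest in p. With fry this call was lost (adjusted p = 0.31), and so were the other 3 of NRas-KO (adjusted p = 1 each). Immediate early genes were called upward there (adjusted p = 0.049, and adjusted p = 0.94 with an estimated correlation). With the code start as a fixed block, which these 3 groups share, limma called 0 genes in either comparison, with 171 and 344 at an unadjusted p under 0.05. The glucocorticoid and cell cycle lists stayed called in NRas-KO under that block (adjusted p = 1.1e-08 and 5.8e-09). In HRas-KO the heart list did (adjusted p = 0.0037) while the ciliated, skeletal muscle and glucocorticoid lists did not (adjusted p = 0.73, 0.19 and 0.067). With fry 0 lists were called in HRas-KO, so the heart call was lost there too. Within the 2 shared code starts HRas-KO gave 0 and 0 called genes (123 and 189 at an unadjusted p under 0.05) from 1 array against 1 and 1 against 2, and NRas-KO 0 and 2 (81 and 681) from 1 against 1 and 2 against 2. A lone array was assumed to vary like the other groups, so a count of 0 there says little. Without NRas-KO replicate 1, 6 genes were called. The cell cycle call was lost without NRas-KO replicate 3 (adjusted p = 0.73), the neutrophil call without Control replicate 1 or NRas-KO replicates 2 or 3 (adjusted p = 0.5, 0.78 and 0.35), and the immediate early call without Control replicate 3 or NRas-KO replicate 2 (adjusted p = 0.86 and 0.47). In HRas-KO the heart call was lost without HRas-KO replicate 2 (adjusted p = 0.13), the ciliated call without HRas-KO replicate 1 (adjusted p = 0.52), the skeletal muscle call without Control replicate 3 or HRas-KO replicates 1 or 3 (adjusted p = 0.97, 0.052 and 0.11) and the glucocorticoid call without Control replicate 2 or HRas-KO replicate 2 (adjusted p = 0.55 and 0.059).

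DKO differed from HRas-KO in 1248 genes (733 higher, 515 lower) and from NRas-KO in 1098 (710 higher, 388 lower). Rnu3a (2.44 and 1.74) and Rasd1 (1.75 and 1.36) were higher against both, and Bst2 (-1.62 and -1.75), Nes (-1.80 and -1.75) and Ly96 (-1.66 and -1.50) lower. Against HRas-KO Cyp2b10 (1.59), Egln3 (1.60) and Rny3 (1.60) were higher and Etv5 (-1.63) and Nppa (-2.86) lower. Nppa was 6.02 ± 0.45 (n = 5) in DKO, 6.05 ± 0.04 (n = 3) in Control and 8.88 ± 2.14 (n = 3) in HRas-KO, whose heart muscle list means were 0.77, 0.89 and 0.17. Against NRas-KO Pi15 (1.48), the tendon regulator Mkx (1.42) and the amino acid transporter Slc38a4 (1.35) were higher and Nexn (-1.47) and Zfp781 (-1.42) lower.

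Interferon genes were called downward against both (camera adjusted p = 8.7e-06 and 6.9e-07, adjusted p = 0.26 and 0.21 with an estimated correlation), with 5 and 4 of 14 members called lower. So were type 2 genes (adjusted p = 5.3e-05 and 0.0011, adjusted p = 0.28 and 0.48 with an estimated correlation), with 3 of 22 members lower in each. With muscle lists as covariates the interferon, type 2 and p53 calls against HRas-KO were lost (adjusted p = 0.22, 0.31 and 0.25). With fry the type 2 call against NRas-KO was lost (adjusted p = 0.061). Against NRas-KO the ERK target list was called downward (adjusted p = 0.0071, adjusted p = 0.48 with an estimated correlation), with Etv5 (-1.33) and Ccnd1 (-1.02) lower. That call was lost with fry (adjusted p = 0.12) and without DKO replicate 3 (adjusted p = 0.096). Sphingolipid genes, a theme of the title and so no independent evidence, were called upward against both (adjusted p = 0.025 and 0.0011), with adjusted p = 0.16 and adjusted p = 0.012 with an estimated correlation and 6 of 45 members higher in each. The call against HRas-KO was lost without HRas-KO replicate 3 (adjusted p = 0.1). In all 10 lists were called against HRas-KO, heart muscle downward and skeletal muscle upward among them (adjusted p = 0.00024 and 0.0084), and 13 against NRas-KO, of which 0 and 1 were called with an estimated correlation. The gene counts fell to 632, 549 and 761 without HRas-KO replicates 1, 2 and 3, and to 691, 500 and 647 without NRas-KO replicates 1, 2 and 3, and no code start was shared. Against HRas-KO the count was 86 with muscle lists and 127 with small RNA rows as covariates, 646 without the 5 arrays highest in skeletal muscle genes and 459 in a fit of those groups alone. Against NRas-KO it was 534 with small RNA rows as a covariate, 171 without those 5 arrays and 312 in a fit of those groups alone. After quantile normalization the split against NRas-KO was 581 higher to 517 lower. All 3 DKO comparisons use the same DKO arrays, so their overlap is partly built in.

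A difference of differences asked whether losing both genes exceeded the sum of the single losses, and 50 genes passed, 31 higher and 19 lower. Etv5 (-1.78 ± 0.23, adjusted p = 0.00041), Nes (-1.91), Gimap4 (-1.30), Gga1 (-0.98) and the Hedgehog receptor Ptch1 (-0.96) were lower than the sum of the single differences, and Mgat4a (1.29), Rabac1 (1.16), Sesn1 (1.41), Perp (1.27) and Ms4a4d (1.07) were higher than that sum. Glucocorticoid response genes (camera adjusted p = 4.7e-05, adjusted p = 0.037 with an estimated correlation) and sphingolipid genes (adjusted p = 0.0069, adjusted p = 0.037 with an estimated correlation) were called upward, with Cdkn1a (0.82) the 1 glucocorticoid member called and no sphingolipid member called. Glucocorticoid list means were 0.08 to 0.28 in Control, 0.01 to 0.08 in HRas-KO, -0.21 to -0.04 in NRas-KO and 0.13 to 0.35 in DKO. Low values in the single deletions therefore entered that call, and the list was not called in DKO against Control. Counts were 98, 23 and 10 without Control replicates 1, 2 and 3, 24 without HRas-KO replicate 2, 25, 25 and 26 without NRas-KO replicates 1, 2 and 3, and 94 and 33 without DKO replicates 4 and 5. After quantile normalization the split was 26 higher to 33 lower, and without the 5 arrays highest in skeletal muscle genes limma called 0 genes (1585 at an unadjusted p under 0.05).

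NAC arrays differed from untreated arrays in every genotype: 3002 genes in controls (1743 higher, 1259 lower), 2625 in HRas-KO (1493, 1132), 1425 in NRas-KO (635, 790) and 2706 in DKO (1273, 1433). NAC was given to the pregnant females, while n counts their newborn animals. All 3 HRas-KO+NAC arrays had the same code start, as did 3 of 4 Control+NAC arrays. If a code start is a litter, animals of 1 treated female stand there as replicates. These comparisons share no arrays, and 245 genes were called higher and 301 lower in all 4, where independent lists would give 0.19 and 0.15. The lists are not independent, since genotypes shared code starts within an arm and 1 estimate of the spread. A batch between the arms would also raise the overlap, so its size does not tell NAC from batch. The basement membrane proteoglycan Hspg2 fell by 1.47 to 1.66, the histone methyltransferase Kmt2d by 1.35 to 1.49, the nuclear RNA Neat1 by 1.05 to 1.83, the receptor Lrp1 by 1.10 to 1.20 and the collagen Col1a1 by 1.01 to 1.26. The myosin light chain Myl12a rose by 1.34 to 2.28, the vesicle protein Vamp7 by 0.78 to 1.59 and Klhl28 by 0.91 to 1.20. Across genes the differences correlated at 0.396 to 0.785 between pairs of genotypes, and genes are not independent replicates.

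In DKO, NAC arrays also had less Rasd1 (-1.60), Cyp2b10 (-1.23), the death receptor Tnfrsf10b (-1.37) and the aspartate transaminase Got1 (-1.24), and more Nabp1 (1.61), Olfm4 (1.28), Ctla2b (1.21), Gimap4 (1.17), Azin1 (1.16), Usp12 (1.13) and Vmp1 (1.12). Alveolar type 1 genes fell in 6 of 18 members, with Krt7 (-0.66) and Spock2 (-0.69), and none rose (camera adjusted p = 0.00091). Type 1 list means were 0.32 and 0.30 in DKO replicates 1 and 3, against 0.09, 0.05 and 0.06 in DKO replicates 2, 4 and 5 and -0.17 to 0.00 in DKO+NAC. Heart muscle genes fell in 5 of 12, with Myh6 (-1.35) and Actn2 (-1.20) (adjusted p = 0.0052), and skeletal muscle genes in 3 of 12, with Acta1 (-1.76) (adjusted p = 0.00056). Fibroblast and matrix genes fell in 7 and rose in 1 of 19, with Col1a1 (-1.24) and Pdgfrb (-0.77) (adjusted p = 0.016). NRF2 and glutathione genes, the response to oxidants, fell in 6 and rose in 1 of 21, with Gsta4 (-0.81) and Nqo1 (-0.53) (adjusted p = 0.029), complex IV in 4 of 16 with Cox8a (-0.67) (adjusted p = 0.017), erythroid genes in 5 of 10 with Slc4a1 (-0.97) (adjusted p = 0.0052), and glucocorticoid genes in 3 of 17 with Cdkn1a (-0.84) (adjusted p = 0.0078). None kept its call with an estimated correlation (adjusted p = 0.34 or 0.54). Without the array labelled DKO+NAC replicate 4 the fibroblast, complex IV and NRF2 calls were lost (adjusted p = 0.077, 0.11 and 0.052), and the NRF2 call also without DKO replicates 4 or 5 (adjusted p = 0.16 and 0.09).

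In controls the NAC arrays had lower endothelial genes, 5 of 20 with the endoglin gene Eng (-0.95) (adjusted p = 0.016), and higher cell cycle genes, 5 of 29 with Pcna (0.61) (adjusted p = 0.0024). The heart muscle, skeletal muscle and glucocorticoid lists were also called downward (adjusted p = 0.022, 0.018 and 0.045). Mean values went from 0.17 to -0.21 for heart muscle, from 0.17 to -0.34 for skeletal muscle and from 0.15 to -0.10 for endothelial genes. All 5 calls were lost with an estimated correlation (adjusted p = 0.64 or 0.85). Rabggtb rose by 2.62 in controls and 2.40 in HRas-KO. In NRas-KO, fibroblast and matrix genes fell in 6 of 19 (adjusted p = 9.7e-05, adjusted p = 0.1 with an estimated correlation), and Krt1 fell by 1.95, from 5.92 ± 1.78 (n = 3, 4.07 to 7.63) in NRas-KO to 3.97 ± 0.09 (n = 3). The ciliated, endothelial, smooth muscle, heart muscle, skeletal muscle, cell cycle, ERK target and immediate early lists were also called downward there (adjusted p = 0.0014, 0.0017, 0.022, 0.0017, 0.0027, 0.041, 0.0034 and 0.0027), and none of the 9 kept its call with an estimated correlation. In HRas-KO the endothelial, fibroblast and heart muscle lists were called downward (adjusted p = 0.027, 0.031 and 0.031), each lost with an estimated correlation (adjusted p = 0.71, 0.71 and 0.72). In HRas-KO the unfolded protein response list was called upward with Dnajb9 (0.65) (adjusted p = 0.027, adjusted p = 0.72 with an estimated correlation), a call lost without HRas-KO replicate 2 (adjusted p = 0.15). With array medians subtracted the split in DKO was 909 higher to 1656 lower. No code start occurred in both arms, so NAC and collection batch cannot be told apart. Counts dropped over 1.5-fold without Control replicates 1 and 2 (1655 and 1319), HRas-KO replicate 2 (1658), HRas-KO+NAC replicates 1 and 3 (1374 and 1731), NRas-KO replicates 1 and 2 (821 and 711) and NRas-KO+NAC replicates 1 and 2 (939 and 804).

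Within the NAC arm no gene was called between any deletion and Control+NAC. At an unadjusted p under 0.05 limma gave 2116 genes for DKO+NAC, 1408 for HRas-KO+NAC and 2321 for NRas-KO+NAC, where 1109 are expected by chance. In DKO+NAC the smallest p-values, none passing, belonged to Nras (-0.58 ± 0.11, adjusted p = 0.12), Krt90 (0.59), Zfp273 (-0.76), Timm22 (-0.37) and the phosphoinositide kinase subunit Pik3r3 (-0.59). HRas-KO+NAC had Pik3r3 (-0.61), Zfp273 (-0.74), Vmo1 (0.41), Olfr982 (0.42) and Olfr705 (-0.68), and NRas-KO+NAC had Nras (-0.63), Gemin7 (0.53), Sectm1b (0.50), Cts8 (-0.69) and Pik3r3 (-0.62). These 3 comparisons share the Control+NAC arrays, whose chance deviations enter each.

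Cell cycle genes were called downward in DKO+NAC (28 of 29 estimates negative, camera adjusted p = 6.8e-16) and in NRas-KO+NAC (27 of 29, adjusted p = 7.1e-09), with Ccna2 at -0.99 and -0.71 and no member called over all genes, though 13 in DKO+NAC passed adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.9 and 0.98). List means were -0.53, -0.20, 0.07 and 0.05 in DKO+NAC replicates 1 to 4, 0.09, -0.38 and 0.02 in NRas-KO+NAC replicates 1 to 3, and 0.54, 0.27, 0.24 and 0.00 in Control+NAC replicates 1 to 4. The lowest arrays of DKO+NAC and NRas-KO+NAC shared a code start that no Control+NAC array had. With the 2 wrongly matched members removed from their lists, 4 more lists were called downward in DKO+NAC: glycolysis, heart muscle, ciliated cells and the unfolded protein response (adjusted p = 0.035, 0.041, 0.048 and 0.049). Of these only glycolysis (adjusted p = 0.076 before) lost a member. The others kept all members and moved from a camera adjusted p of 0.061 each through the adjustment over lists. None of the 4 was called with an estimated correlation (adjusted p = 0.9 each). Heart muscle genes were called upward in HRas-KO+NAC (adjusted p = 0.021, adjusted p = 0.97 with an estimated correlation), a call lost without Control+NAC replicates 1, 2 or 3 or HRas-KO+NAC replicate 2 (adjusted p = 0.12, 0.056, 0.071 and 0.42). Codes are shared in part across genotypes in this arm, and with the code start as a fixed block limma called 0, 1 and 0 genes (1395, 1000 and 1210 at an unadjusted p under 0.05). The cell cycle list stayed called in DKO+NAC (adjusted p = 4.5e-05) but not in NRas-KO+NAC (adjusted p = 0.93). Within single code starts DKO+NAC gave 0 and 0 called genes (limma, 648 and 2413 at an unadjusted p under 0.05) from 1 array against 3 and 1 against 1. HRas-KO+NAC gave 0 (limma, 971 at an unadjusted p under 0.05) from 3 against 1 and NRas-KO+NAC 0 (1502) from 1 against 1. Each rests on a lone array assumed to vary like the other groups, so these counts say little. Without Control+NAC replicate 2 the counts were 14 for DKO+NAC and 4 for NRas-KO+NAC. Leaving out DKO+NAC replicates 2 and 3 gave 1 and 3, and leaving out the array labelled DKO+NAC replicate 4 gave 1. Without HRas-KO+NAC replicate 3 the count for HRas-KO+NAC was 1, and without Control+NAC replicate 4 that for NRas-KO+NAC was 1.

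The DKO difference itself differed between the arms in 86 genes, 26 higher and 60 lower with NAC. Nes (1.56), Zfp781 (1.53) and Pdlim7 (1.09), lower in untreated DKO, and Ifna4 (1.15) and Olfr1502 (1.45) were relatively higher, and Rnu3a (-1.86), Thbs2, a matrix thrombospondin (-1.22), Cd109 (-1.17), Cep85l (-1.13) and Tmem185a (-1.10) relatively lower. Of these 86 genes 73 were also called between untreated DKO and Control, all 73 with the opposite sign, which is partly built in because both tests use the same untreated arrays. The interferon list was called upward (camera adjusted p = 0.00026) and the cell cycle (adjusted p = 2.4e-06) and cholesterol lists (adjusted p = 0.0049) downward, with no member called and adjusted p = 0.74 each with an estimated correlation. The type 2 list was called upward with Muc1 (0.73) called (adjusted p = 0.029, adjusted p = 0.74 with an estimated correlation), a call lost without Control replicate 1, Control+NAC replicate 2, DKO replicates 1 or 3 or DKO+NAC replicates 1, 2 or 3 (adjusted p = 0.057, 0.054, 0.11, 0.078, 0.093, 0.068 and 0.074). In a limma fit of the 4 groups alone the count was 0, with 2589 genes at an unadjusted p under 0.05. It was 15 and 21 without Control replicates 1 and 2, 15, 26 and 24 without Control+NAC replicates 1, 3 and 4, 148 and 28 without DKO replicates 3 and 5, and 18 and 40 without DKO+NAC replicates 1 and 2. The split was 25 higher to 26 lower after quantile normalization and 23 to 146 with array medians subtracted. Of the 850 genes called without NAC, 479 (56.4%) went the same way with NAC (exact one-sided p = 0.13 over 70 relabelings of the 8 NAC arrays), with a median signed difference of 0.028 against 0.544. Either group can close a difference. Mean Etv5 was 8.57 in Control and 7.98 in Control+NAC, but 7.38 in DKO and 7.53 in DKO+NAC. It was also lower with NAC in HRas-KO (9.01 to 7.79) and NRas-KO (8.71 to 7.79). Mean Perp went from 8.51 to 9.12 in controls and from 9.68 to 9.23 in DKO. Mean Bst2 went from 8.67 to 8.24 in controls and from 6.78 to 7.71 in DKO.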

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

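Tests chosen only after the result was seen were the 2 collection batch tests, the 2 tests of too few arrays, the comparison of code starts, and the fits with Xist, muscle or small RNA covariates or without muscle-rich arrays. Of 205 groups of 4 or 5 values tested, 17 held an array far from the others, and chance gives about 1 in 20 groups, or 10.

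Among named genes, Oasl2 was 5.21 in DKO replicate 5 (the others 5.91 to 6.14), Etv5 7.81 in DKO replicate 4 (7.23 to 7.35) and Myl12a 8.05 in DKO replicate 3 (7.30 to 7.45). Gimap4 was 7.29 on the array labelled DKO+NAC replicate 4 (8.07 to 8.10), Myh6 6.14 in DKO+NAC replicate 1 (5.64 to 5.68) and Krt90 4.51 in Control+NAC replicate 3 (4.15 to 4.19). Among list means, the array labelled DKO+NAC replicate 4 stood apart in type 2 genes at -0.16 (0.02 to 0.04), heart muscle at -0.62 (-0.42 to -0.39) and oesophagus and basal epithelium at 0.27 (-0.21 to -0.15). DKO+NAC replicate 3 stood apart in erythroid genes at -0.10 (0.03 to 0.06) and skeletal muscle at -0.41 (-0.25 to -0.21), and DKO+NAC replicate 1 in immediate early genes at -0.30 (-0.06 to -0.03). DKO replicate 5 stood apart in oesophagus and basal epithelium at 1.28 (-0.09 to 0.09) and DKO replicate 2 in acute inflammation at 0.30 (-0.15 to -0.06). Control+NAC replicate 3 stood apart in fibroblast and matrix genes at -0.15 (-0.03 to -0.01), Control+NAC replicate 1 in thyroid genes at -0.14 (-0.02 to -0.01) and Control+NAC replicate 2 in small RNA rows at -0.23 (0.11 to 0.16).

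The difference between the double deletion and the sum of the single ones passed its own test in 50 genes, with Sesn1 1.41, Mgat4a 1.29, Perp 1.27, Rabac1 1.16, Ms4a4d 1.07, Nes -1.91, Etv5 -1.78, Gimap4 -1.30, Gga1 -0.98 and Ptch1 -0.96 on the log2 scale. The lists called in that test had mean differences of -0.27 (type 2), 0.36 (erythroid), -0.61 (heart muscle), 0.16 (sphingolipid), -0.18 (cell cycle), -0.26 (ERK targets), 0.21 (NRF2), 0.47 (glucocorticoid), 0.32 (cholesterol), -0.45 (interferon) and 0.42 (p53), and of these 11 only the sphingolipid and glucocorticoid lists kept the call with an estimated correlation (adjusted p = 0.037 each, the others 0.25 to 0.76). Heart muscle list means were 0.17 in Control, 0.61 in HRas-KO, 0.18 in NRas-KO and 0.01 in DKO, so high HRas-KO arrays entered the value of -0.61. The DKO difference differed between the arms in 86 genes, with Nes 1.56, Zfp781 1.53, Olfr1502 1.45, Ifna4 1.15, Pdlim7 1.09, Rnu3a -1.86, Thbs2 -1.22, Cd109 -1.17, Cep85l -1.13 and Tmem185a -1.10. The 4 lists called there had mean differences of 0.18 (type 2), -0.45 (cell cycle), -0.40 (cholesterol) and 0.53 (interferon), and 0 of the 4 kept the call with an estimated correlation (adjusted p = 0.74 each). Among 17824 probe sets without a single gene symbol, not used in the comparisons, 440 differed between DKO and Control (201 higher, 239 lower) and 1562 between DKO+NAC and DKO (864 higher, 698 lower).

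Untreated DKO lungs differed from Control in 850 genes. With both muscle lists as covariates 493 of the 850 stayed called, at a median difference of 0.533 against 0.544, and without the 5 muscle-rich arrays, which left 4 arrays, 163 did, at 0.527 with the standard error up from 0.127 to 0.16. The kept sizes argue against carried muscle as the whole source. Xist was high on DKO replicates 1 and 3 and Control replicate 3 and low on the rest, a similar mix that argues against the sex ratio. With groups so alike the Xist covariate, under which 834 stayed called, could change little. A shared Xist term cannot test a difference between sexes within DKO alone. A collection batch of the DKO animals, whose code starts no other group shares, cannot be told apart from the deletions. In the NAC arm 56.4% of the 850 went the same way. Of 70 relabelings 9, the real one included, reached as much, and the second highest share among them was 59.8%. That arm is matched only in part, since DKO+NAC replicates 1 and 2 had code starts that no Control+NAC array had. With small RNA rows as a covariate 161 of the 850 stayed called, at a median of 0.529 with the standard error up from 0.127 to 0.171, so the calls ended mainly through a wider error.

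NAC and untreated lungs differed in 1425 to 3002 genes per genotype. Quantile normalization again gave 2792 genes in controls. RMA already normalizes arrays by quantiles, so this repeat cannot show scaling brought in by that step, and array-wide scaling stays open. With both muscle lists as covariates 1743 of 3002 genes stayed called in controls, 1169 of 2706 in DKO, 1191 of 2625 in HRas-KO and 913 of 1425 in NRas-KO, at median differences of 0.51, 0.487, 0.533 and 0.592 against 0.514, 0.473, 0.563 and 0.554 before. Standard errors grew from 0.129 to 0.148, 0.117 to 0.153, 0.139 to 0.161 and 0.137 to 0.159, so calls ended mainly through wider errors, and the kept sizes argue against less muscle as the whole source. With Xist as a covariate 2877 of 3002 genes stayed called in controls, 1839 of 2706 in DKO, 2130 of 2625 in HRas-KO and 1364 of 1425 in NRas-KO. Xist was high on all DKO+NAC and low on all HRas-KO+NAC arrays. Median differences there were 0.457 in DKO and 0.568 in HRas-KO, against 0.473 and 0.563 before. With 0 code starts found in both arms, a collection or array batch between the arms cannot be told apart from NAC, and an effect of NAC itself stays open.

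Between the 2 code starts shared by Control, HRas-KO and NRas-KO, with the group as a block, 713 genes were called on 8 arrays, and between 2 NAC codes limma called 0 on 10 arrays (1746 at an unadjusted p under 0.05).

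No gene passed between DKO+NAC and Control+NAC. For the 850 genes called between DKO and Control, the median difference with NAC in the untreated direction was 0.0283 (SD over genes 0.163, 0.0168 to 0.0327 leaving out 1 array) against 0.544 untreated, which argues against too few arrays hiding differences of the untreated size in these genes as a set. A single difference of that size can be missed: Nras was -0.61 untreated and -0.58 with NAC, yet not called there (limma adjusted p = 0.12). Too few arrays to call smaller differences cannot be told apart from none, since 3 of 35 splits gave as many genes as the real 2116 at an unadjusted p under 0.05 (highest other 2821). Leaving out the array labelled DKO+NAC replicate 4, whose values have the narrowest spread, gave 1 gene. Xist as a covariate, tried since all 4 DKO+NAC arrays were high in Xist, gave 0 by limma (1831 at an unadjusted p under 0.05). A fit with fewer arrays, or with a covariate nearly constant in DKO+NAC, can itself miss differences. Neither fit can therefore decide whether that array or sex hides any. An effect of NAC stays open as an untested explanation.

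Other splits of the same arrays were counted for each comparison. They treat arrays as independent, while arrays sharing a code start correlated at 0.15 on average, so they can exclude chance among single arrays but not among whole code starts. For DKO against Control 1 of 56 splits, the real one, reached 850 genes, and the highest other gave 759. For DKO against HRas-KO 1 of 56 reached 1248 (highest other 708) and for DKO against NRas-KO 1 of 56 reached 1098 (highest other 1013). For these 3 the real split ranked first, the smallest share that 56 splits allow. This argues against chance among single arrays without excluding it. Yet each highest other split set DKO replicates 1, 3 and 5, the DKO arrays highest in skeletal muscle genes, apart from all remaining arrays, which points to a structure within the DKO group. For DKO+NAC against DKO 1 of 100 drawn splits reached 2706 (highest other 871), and for Control+NAC against Control 1 of 35 reached 3002 (highest other 1033), which argues against chance among single arrays only. In the non-additivity test 4 of 100 splits reached 50, and in the test of the difference between arms 4 of 100 reached 86. These shares lie just under 0.05, and the highest others, 679 and 536, lay several times above the real counts and point to a structure of the samples. In fits of the compared groups alone the counts were 12 and 0 (limma, 2589 at an unadjusted p under 0.05 for the latter), and leaving out 1 array took them as low as 10 and 15, so chance is not taken as excluded for either. Within the NAC arm the real counts were 0, which all 35 splits of each comparison reach by construction, so chance is not excluded (limma, highest others 5 for DKO+NAC, 2 for HRas-KO+NAC and 30 for NRas-KO+NAC, with 2116, 1408 and 2321 genes at an unadjusted p under 0.05 in the real split). The 10 splits are too few for a share under 0.05 for HRas-KO and NRas-KO against Control, where all 10 reached the real 0 (limma, highest others 0 and 1, with 190 and 231 genes at an unadjusted p under 0.05). They are too few as well for HRas-KO+NAC against HRas-KO (2625, highest other 1) and NRas-KO+NAC against NRas-KO (1425, highest other 0), where 1 split reached the real value.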

How the results depend on the processing

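The Xist, muscle and small RNA covariates, the fits without muscle-rich or narrow-spread arrays, those within 1 code start and the lists without 2 wrongly matched members were chosen after seeing the data. Of the values of named genes under the alternatives other than leaving out 1 array, 5847 kept direction and side of the threshold, 518 lost the threshold, 138 gained it and 32 changed sign, and for list calls 466 stayed and 180 were lost. Where not stated, the cause was not tested.

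Counts of called genes moved by over 1.5 times as follows. On all rows of the table they were 102 for non-additivity, 4130 for DKO+NAC against DKO, 35 for DKO+NAC and 6 for NRas-KO+NAC against Control+NAC, and 171 for the difference between arms. Without the dimmest 40% of rows non-additivity gave 85, with fewer genes tested. Quantile normalization again gave 51 for the difference between arms and 5 lists for DKO+NAC against DKO. Subtracted array medians gave 1 for DKO+NAC, 1 for NRas-KO+NAC and 169 for the difference between arms. Array weights gave 2162 for DKO against HRas-KO, 321 for non-additivity, 4143 for HRas-KO+NAC against HRas-KO, 1 for DKO+NAC against Control+NAC and 136 for the difference between arms, and the lowest weight (0.41) fell on the array labelled DKO+NAC replicate 4.

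Same-numbered arrays shared only a number, with 13 of 37 pairs correlating over 0.1. With the replicate block 1 gene was called for DKO+NAC, 1 for HRas-KO+NAC and 2 for NRas-KO+NAC against Control+NAC, and Nras in HRas-KO+NAC was 0.00. The code start as a random block (consensus correlation 0.12) gave 50 for the difference between arms, and as a fixed block 1 for HRas-KO+NAC and 3 lists for DKO+NAC against Control+NAC. The fixed block could not be fitted for comparisons whose groups share no code.

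Xist as a covariate gave 57 for the difference between arms, 5 lists for DKO+NAC against DKO and 3 for DKO+NAC against Control+NAC. Muscle lists as covariates gave 544 for DKO against Control, 86 against HRas-KO, 5 for non-additivity, 1406 for DKO+NAC against DKO, 1996 for controls and 1270 for HRas-KO with NAC, with 9 lists for DKO+NAC against Control+NAC and 7 for the difference between arms; muscle genes and lists were not refitted there. Small RNA rows as a covariate gave 183, 127 and 534 for DKO against Control, HRas-KO and NRas-KO, 28 for non-additivity and 13 for the difference between arms. Without the 5 muscle-rich arrays these were 213, 646, 171, 0 (limma, 1585 at an unadjusted p under 0.05) and 57, and 1682 for DKO+NAC against DKO. Without the 3 narrow arrays NRas-KO+NAC against NRas-KO gave 903, DKO+NAC against Control+NAC 1 and the difference between arms 7 lists.

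A fit of the compared groups alone, with fewer arrays behind the spread, gave 122, 459 and 312 for DKO against Control, HRas-KO and NRas-KO, 12 for non-additivity, 1476 and 486 for NAC in DKO and NRas-KO, and 0 for the difference between arms (2589 at an unadjusted p under 0.05). Requiring 1.5-fold left 349, 472 and 458 for DKO, and 766, 1026, 1174 and 612 for NAC in DKO, controls, HRas-KO and NRas-KO. Within 1 code start 2 genes were called for NRas-KO against Control. With an estimated correlation 0 lists were called in DKO against Control, DKO+NAC against DKO, DKO+NAC against Control+NAC and the difference between arms, against 6, 8, 1 and 4, and fry gave 0 and 1 in the last pair. Without the 2 members matched to another gene, 5 lists were called in DKO+NAC against Control+NAC.

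Leaving out 1 array gave 321 to 875 for DKO against Control, 549 to 1246 against HRas-KO, 500 to 1183 against NRas-KO, 0 to 0 for HRas-KO and 0 to 6 for NRas-KO against Control, 10 to 98 for non-additivity, and 15 to 148 for the difference between arms. NAC counts ran from 2045 to 2838 in DKO, 1319 to 2864 in controls, 1374 to 2232 in HRas-KO and 711 to 1359 in NRas-KO. Against Control+NAC they ran from 0 to 14 for DKO+NAC, 0 to 1 for HRas-KO+NAC and 0 to 4 for NRas-KO+NAC. Lists ran from 5 to 11 for DKO against Control, 7 to 11 for DKO+NAC against DKO, 1 to 9 for DKO+NAC against Control+NAC and 2 to 7 for the difference between arms.

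The following values changed sign. Nras with NAC in HRas-KO (0.02) was -0.03 after quantile normalization, -0.01 with the random block, -0.10 with muscle covariates, and -0.05 and -0.04 without HRas-KO replicate 2 or HRas-KO+NAC replicate 1. Nras with NAC in NRas-KO (0.01) was -0.00 with medians subtracted, -0.05 with muscle and -0.02 with small RNA covariates, -0.13 without narrow arrays, and -0.05, -0.01 and -0.04 without NRas-KO replicate 3 or NRas-KO+NAC replicates 2 or 3. Its difference between arms (0.03) was -0.03 with medians subtracted, -0.05 with weights, -0.13 with the small RNA covariate, -0.06 without muscle-rich and -0.08 without narrow arrays, and -0.02, -0.01, -0.02 and -0.08 without Control replicate 3, Control+NAC replicate 1, DKO replicate 3 or the array labelled DKO+NAC replicate 4. Nras in HRas-KO+NAC (-0.04) was 0.05 with muscle covariates, 0.02 within 1 code and 0.01 without Control+NAC replicate 3. Nras in HRas-KO (0.02) was -0.03 with the small RNA covariate and -0.06, -0.01 and -0.02 without Control replicate 1 or HRas-KO replicates 1 or 3, and with that covariate it was 0.06 in DKO against NRas-KO and 0.08 for non-additivity. Myh6 in HRas-KO+NAC was -0.01 with the fixed block and -0.28 within 1 code. Drc1 in HRas-KO was 0.07 with muscle covariates and 0.00 within 1 code, and Acta1 in DKO against HRas-KO was -0.05 without muscle-rich arrays. Within 1 code HRas-KO had Tnnt2 at -0.06, Myh6 at -0.00 and Zbtb16 at 0.06, and NRas-KO had Krt1 (1.72 over all its arrays) at -0.07, Mmp9 at 0.25, Mmp8 at 0.00, Retnlg at 0.23, Ube2c at -0.07 and Fkbp5 (-0.52 over all its arrays) at 0.21, from 1 or 2 arrays a group whose spread is taken from the other groups.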

Other observations

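The test of the microRNA cluster was chosen only after related results were seen, as was the window around Nras in DKO+NAC. Muscle and sex transcripts varied between single arrays in ways the labels do not name. The mean of the skeletal muscle list ran from -0.19 to 1.41 over the 5 DKO arrays, and the heart muscle list averaged 0.61 ± 0.39 (SD, n = 3) in HRas-KO, 0.01 in DKO and -0.46 ± 0.11 (n = 4) in DKO+NAC. Xist, the transcript of the inactive X chromosome, was 10.84 to 11.07 on all 4 DKO+NAC arrays and 4.38 to 4.60 on all 3 HRas-KO+NAC arrays, while the other groups held both high and low arrays.

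Genes beside Nras were compared with windows of neighbouring genes elsewhere, in the gene order of the RefSeq annotation GRCm38.p6, since sequence of the targeted stem cells may stay linked to a deleted gene. In NRas-KO against Control the 100 nearest measured genes had a mean absolute moderated t of 0.721, the 98.4th percentile of 20109 windows (median window 0.592). In DKO against Control the percentile was 78.1, so the condition set for both comparisons was not met and the explanation stays open. In the NAC arm, which was not part of that condition, the percentiles were 98.5 for NRas-KO+NAC and 99 for DKO+NAC.

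The mean of 43 microRNAs encoded between Meg3 and Dio3, an imprinted cluster, was set against the mean of the 17 glucocorticoid response genes, as deviations from group means, since stage or time after birth may differ between animals of a group. Over 28 arrays Pearson's r was -0.291 and Spearman's rho -0.349 (permutation p = 0.23 and 0.14, two-sided, Benjamini-Hochberg adjusted p = 0.31 for r over 4 relations). Without the 2 arrays farthest in the glucocorticoid list r was -0.494 (permutation p = 0.046, adjusted p = 0.18). It was -0.226 over the 14 untreated arrays (permutation p = 0.52) and -0.48 over the 14 NAC arrays (permutation p = 0.19), so the relation was not established.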
